A study of Mus musculus with 6 samples.

How the data were processed

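The series holds 6 CUT&RUN libraries from splenic CD8 T cells of mice on day 8 after infection, 3 labelled with a Fli1 antibody and 3 as IgG controls. Groups were taken from the sample titles. The antibody label of the first IgG control names the Fli1 antibody, while the other IgG libraries name an anti-rabbit IgG, and the series' design text speaks of wild-type and knockout genotypes that the sample labels do not give. Neither point could be settled here, and no sample was regrouped. No values per library were analysed here, so the depth per library is unknown, and no fit across samples, replicate comparison or test between Fli1 and IgG was made.

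Both deposited files describe the pooled Fli1 peaks, a list of positions with a score and an annotation of the same peaks. The submitters' processing notes list Bowtie2 2.3.4.1, Picard 1.96, SAMtools 1.1, bedtools 2.28.0, MACS2 2.1 and HOMER 4, with builds mm10 and GRCm38, without role or order. Per the file headers, the peaks are a pooled Fli1 list made in MACS2's broad mode with a p of 1e-08 and an FDR of 5e-05, and HOMER's annotatePeaks.pl assigned each to the nearest TSS in mm10. Whether and how the IgG libraries served as control for peak calling is not given in the sources used here. The deposited score is a whole number from 0 to 244 whose meaning is not given. It was used to rank, filter and compare peaks within the list, and a check on chromosome X took it as if proportional to signal. Pooling can let a region strong in a single library pass as a peak, and the stringent thresholds leave out weak binding, so a gene without a peak is not shown to be unbound. The nearest TSS need not be the gene a peak acts on.

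The files paired 1443 of 1447 peaks with equal position and score. In the other 4, the deposited annotation had shifted columns, and these peaks, with 1 more on unplaced sequence, were left without a gene. Coordinates are given 1-based in mm10. Peaks within 1 kb of the TSS were called promoter peaks and those further away distal. Genes came from a RefSeq table of GRCm38.p6, the same build, matched by gene identifier. The background was 21027 protein-coding genes with a curated transcript on chromosomes 1 to 19, X and Y. The nearest gene of 1274 peaks was in it, and 168 peaks were nearest to another gene, 137 of these a non-coding RNA. Of 382 intron peaks with a known host transcript, the nearest TSS belonged to another gene in 90.

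The 30 gene lists, the 24 genes of interest, the rule for named genes and the tests were fixed before the data were examined. The lists cover T cell function, transcription factor families, housekeeping complexes, other cell types and control tissues, and 3 of their genes were not in the reference table. Each list was compared with all other background genes by a two-sided Fisher's exact test, with the conditional odds ratio and its exact 95% interval. Adjustment by Benjamini-Hochberg ran over the 30 lists within each class of peaks (all, promoter and distal), not across the 3 classes, which share peaks. Genes are not independent replicates, and these p-values describe this 1 peak list, not the spread between mice. Shares carry Wilson 95% intervals, and intervals and the limits given for a count of 0 (3 counts of the total) cover counting error only. The score of promoter and distal peaks was compared by 100000 permutations of the difference in medians. Random placement of peaks used the ends of coding genes, since no genome was used here. For the same reason motif content was not analysed here, although it had been planned.

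Named genes are the 24 fixed genes, the 10 highest-scoring peaks, up to 5 members with the highest score from each list that passed and each CD8 T cell list, and the 10 genes with most peaks. Other genes named in the text are the members behind a count, or were chosen after their values were seen. The alternatives tried were other distance limits, peaks with at least the median score, peaks outside repeats, merged peaks, a smaller background, the deposited promoter class, assignment of peaks inside a gene to that gene, and a logistic model with the log length of a gene's territory, taken as its span plus the nearer part of the gap to each neighbour. TSS positions had been planned for the territory, but the gene table used here gives spans without strand. That model was tested by a likelihood ratio, which is approximate for lists with few peaks, and adjusted over the lists with at least 1 peak.

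The list test was tested on simulated data at the rate of distal peaks. With a true odds ratio of 10 it called the T cell receptor signalling list in 92% and the adhesion list in 96% of 100 sets. With a true odds ratio of 5 it called the effector list of 31 genes in 32%, so moderate effects in short lists can be missed. Lists with no effect were called in 0.5%. A list of 60 genes with long territories and no effect was drawn once, and 20 sets of peaks were simulated by territory length alone. Fisher's exact test called this list in 85% of the sets and the logistic model in 0%. A list of long genes can thus pass the main test for distal peaks without an effect. The simulated peaks followed the same territory lengths that the model adjusts for, so the 0% holds only where that measure is right. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.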

Results

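The data are a map of peaks called from libraries made with an antibody against Fli1, a transcription factor of the ETS family, in CD8 T cells taken from the spleens of C57BL/6 mice on day 8 after infection with lymphocytic choriomeningitis virus Clone 13, a strain that sets up a chronic infection. The assay was CUT&RUN, in which an antibody brings a nuclease to a protein on chromatin and the DNA that is cut loose is sequenced. The sample titles give 3 libraries for Fli1 and 3 for an IgG control, although the antibody label of the first IgG library names the Fli1 antibody. The Fli1 libraries are represented by 1 pooled peak list with its gene annotation, so a peak has no replicate check and no error between mice. The depth of each library is unknown, and the Fli1 and IgG libraries could not be compared with each other here. Each peak's score is the authors' own value and is used to rank, filter and compare peaks within the list.

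The first question was where Fli1 peaks lie relative to genes. Peaks concentrated at transcription start sites (TSSs): 676 of 1442 annotated peaks (46.9%, Wilson 95% interval 44.3 to 49.5) were centred within 1 kb of the nearest TSS. A further 137 peaks lay 1 to 5 kb away and 334 lay 10 to 50 kb away. By the deposited annotation, 633 of 1447 peaks were in promoters (43.7%, interval 41.2 to 46.3), 383 in introns (26.5%, interval 24.3 to 28.8) and 377 between genes (26.1%, interval 23.9 to 28.4). The remaining classes were small, with 17 peaks in 5' UTRs, 14 at transcription termination sites, 7 in exons, 6 in 3' UTRs and 5 in non-coding transcripts.

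**Figure D1:**
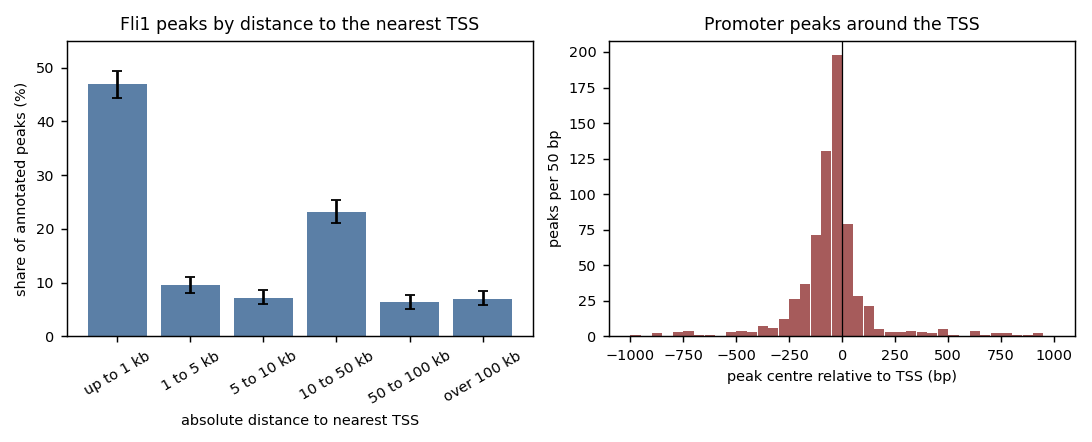
Left, share of the 1442 annotated Fli1 peaks (percent) in each range of absolute distance to the nearest TSS, with Wilson 95% intervals; right, number of promoter peaks per 50 bp by the position of the peak centre relative to the TSS (bp, negative is upstream). The left bar for distances up to 1 kb stands at 46.9%, and the promoter peaks on the right gather just upstream of the TSS, with a median of -43 bp.

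Promoter peaks sat just upstream of the TSS, at a median of -43 bp, and 509 of the 673 that were off the TSS itself lay upstream (75.6%, interval 72.2 to 78.7, exact binomial p = 5.37e-42, two-sided). Among peaks on chromosomes 1 to 19 and X, 631 of 1428 (44.2%) were centred within 1 kb of either end of a coding gene. In each of 1000 random placements, as many points were put on each chromosome between its outermost coding genes. Their mean was 3.20% and their highest value 4.83% (one-sided permutation p = 0.001, the smallest that these placements can give). Promoter peaks had a higher score than distal ones, with medians of 18 and 14 (permutation p = 6e-05, two-sided). The 766 distal peaks had a median distance of 18.6 kb from the nearest TSS. Peaks were narrow, with a median width of 86 bp (quartiles 62 and 134 bp) and a range of 50 to 4549 bp. The share within 1 kb rose to 52.7% among peaks with at least the median score of 16.

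The strongest peaks lay at promoters, in an intron, in a CpG island and in satellite repeats. Among the 10 highest scores, the peak at Ublcp1, a phosphatase of the nuclear proteasome, scored 236 (mm10 chromosome 11, 44470484 to 44470655, promoter). Nr1h2, a liver X receptor, had a promoter peak with a score of 162 (chromosome 7, 44553915 to 44554127), and Uba6, a ubiquitin-activating enzyme, one of 156 (chromosome 5, 86172861 to 86172947). Srsf5, a splicing factor, and Hif1an, which hydroxylates HIF1A, had promoter peaks of 144 and 141. Tnk2, a tyrosine kinase, had a peak of 159 in intron 1 of 13, 6.6 kb from the TSS (chromosome 16, 32651129 to 32651350). The highest score, 244, belonged to a peak between genes in a CpG island 32.2 kb from the TSS of Pisd (chromosome 5, 32713950 to 32714403). The other 3 of these 10 peaks, with scores of 163, 147 and 143, lay in satellite repeats on an unplaced contig, nearest to the pseudogene Pisd-ps3.

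The next question was which genes lie nearest to Fli1 peaks. Of 21027 protein-coding genes, 1170 were nearest to at least 1 peak, 634 of them through a promoter peak and 572 through a distal one. Distal peaks lay near genes of CD8 T cell function. Genes of effector CD8 T cells were nearest to a distal peak in 10 of 31 cases (odds ratio 17.3, 95% interval 7.24 to 38.6, adjusted p = 8.16e-08 by Fisher's exact test), T cell receptor signalling genes in 11 of 41 (odds ratio 13.3, interval 6.00 to 27.6, adjusted p = 8.2e-08) and adhesion and migration genes in 11 of 42 (odds ratio 12.9, interval 5.82 to 26.6, adjusted p = 8.2e-08). Memory and progenitor genes followed with 6 of 32 (odds ratio 8.33, interval 2.79 to 20.8, adjusted p = 0.00117 by the same exact test), a call that ended with at least the median score (2 genes, odds ratio 5.19, adjusted p = 0.232).

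**Figure D2:**
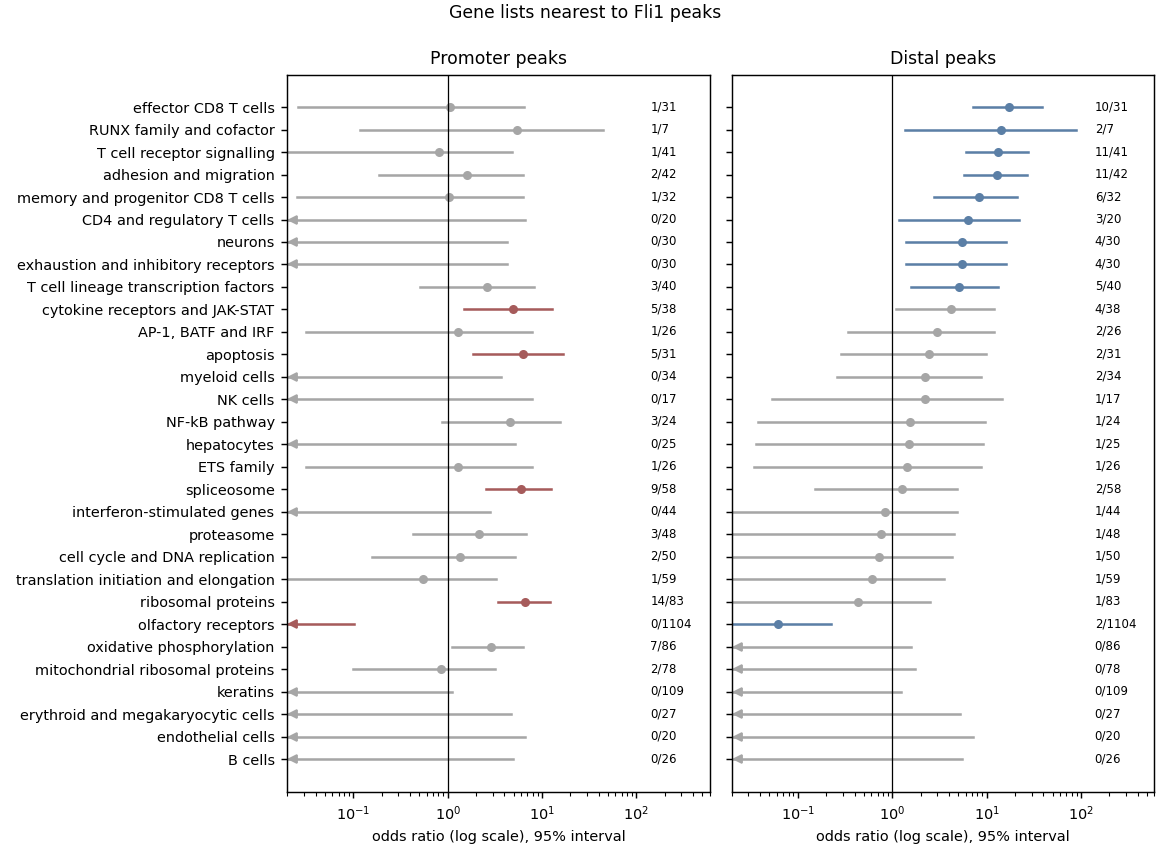
Odds ratio (log axis) of a gene in each list being nearest to a promoter peak (left) or a distal peak (right), with 95% intervals; coloured lists pass an adjusted p of 0.05, arrowheads mark an odds ratio of 0, and the counts give genes with a peak over genes in the list. Effector CD8 T cell genes reach 17.3 for distal peaks, and ribosomal protein genes 6.65 for promoter peaks.

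Among effector genes, the cytokine gene Tnf had a peak with a score of 76 in intron 2 of 2, 1.4 kb from its TSS (chromosome 17, 35200605 to 35200691). Gzmb, which encodes the cytotoxic protease granzyme B, had a pair of peaks between genes, 25.7 and 34.6 kb upstream, with scores of 9 and 62 (chromosome 14, 56287967 to 56288025 and 56296873 to 56297002). Ifng, which encodes interferon gamma, lay between a peak 21.7 kb upstream and a peak 29.8 kb downstream of its TSS, with scores of 6 and 11 (chromosome 10, 118419241 to 118419376 and 118470788 to 118470882). Fasl, a death ligand, had a peak of 32 at 21.8 kb, Prdm1, which encodes the transcription factor Blimp-1, one of 26 at 29.0 kb, and the chemokine gene Ccl5 one of 21 in a LINE repeat at 19.8 kb. Il2ra, Itgax, Prf1 and S100a4 made up the rest of the effector genes with a distal peak.

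Among T cell receptor signalling genes, Cd28, the co-stimulatory receptor, had 2 peaks in intron 1 of 3, 9.7 and 12 kb from its TSS, with scores of 9 and 52 (chromosome 1, 60756016 to 60756071 and 60758366 to 60758437). The nearest TSS of a peak of 56 was that of Themis, a regulator of T cell receptor signal strength, but the peak lay 74.3 kb upstream, in intron 30 of 30 of another gene, Ptprk. Cd2, an adhesion and co-stimulatory receptor, had a peak of 36 at 13 kb, at a transcription termination site. The adaptor genes Sla2 and Lcp2 had intron peaks of 27 and 24, 9.3 and 17.3 kb from their TSSs. Cblb, Cd3d, Dgka, Fyn, Ptprc and Rasgrp1 also had a distal peak. Among adhesion and migration genes, Cytip had a peak of 55 in intron 7 of 7 and Icam2 one of 38 at 5.4 kb upstream. The chemokine receptor genes Cxcr4, Cxcr5 and Cxcr6, the integrin genes Itga4, Itgal and Itgb1, and the sphingosine phosphate receptor genes S1pr1 and S1pr4 were in the same count. Memory and progenitor genes with a distal peak were Cd27, Cxcr5, Klf3, Lef1, Ly6c2 and S1pr1.

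Of 30 genes for exhaustion and inhibitory receptors, 4 had a distal peak (odds ratio 5.53, interval 1.4 to 16, adjusted p = 0.0318 by Fisher's exact test). Havcr2, which encodes the inhibitory receptor TIM-3, had a peak of 11 in intron 4 of 6, 12.1 kb from its TSS (chromosome 11, 46466953 to 46467016). Ctla4, another inhibitory receptor, had a peak of 21 in intron 1 of 3. Tox, a transcription factor of exhausted T cells, had a peak of 29 in intron 1 of 8 and one of 7 in a repeat of intron 3 of 8 (chromosome 4, 6902221 to 6902299 and 6817397 to 6817460). These lay 88.5 and 173.3 kb from its TSS, and Maf had a peak of 21 that lay 306.3 kb away. This call ended with peaks beyond 5 kb (3 genes, odds ratio 4.96, adjusted p = 0.104 by Fisher's exact test) and with territory length in a logistic model (odds ratio 4.68).

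**Figure D3:**
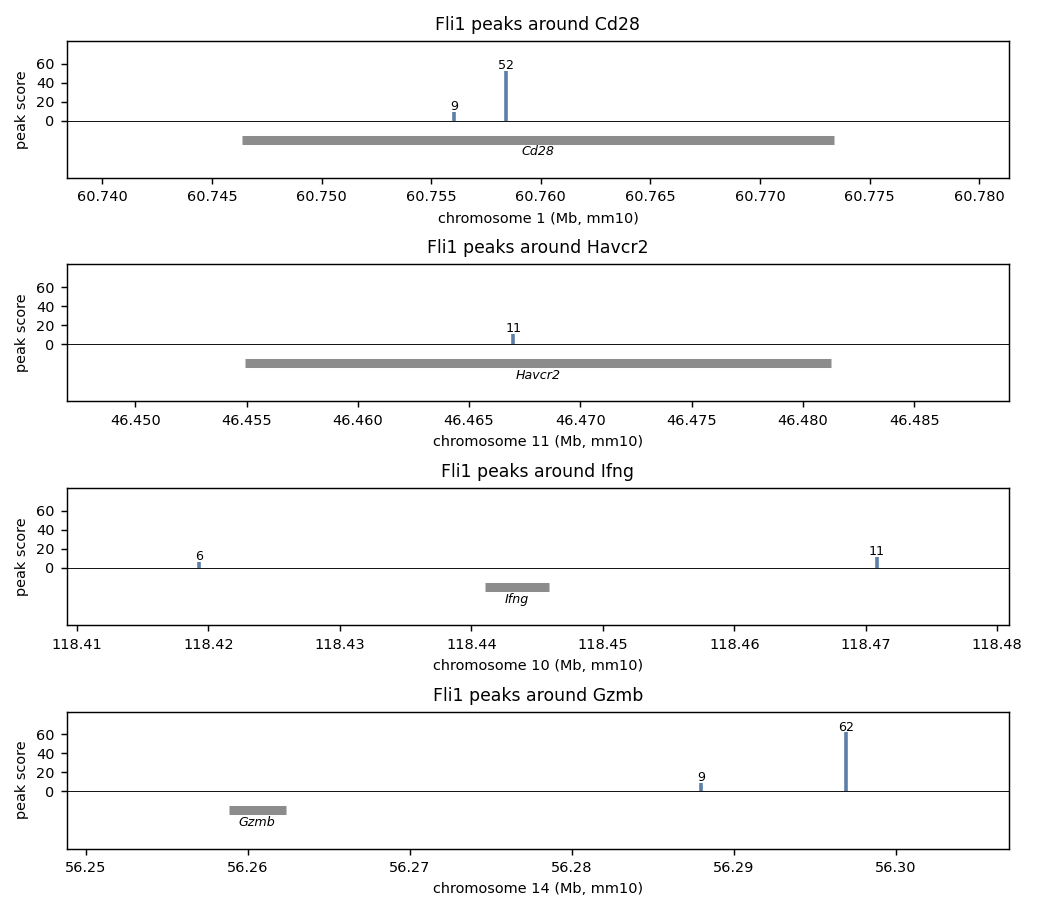
Fli1 peaks around Cd28, Havcr2, Ifng and Gzmb; the horizontal axes give mm10 positions (Mb), grey bars the spans of coding genes, and blue lines the peaks, with their score as height. The peaks at Cd28 and Havcr2 lie inside the gene, and those at Ifng and Gzmb lie outside it.

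Another 4 lists had distal peaks more often than other genes, and olfactory receptor genes less often (2 of 1104, odds ratio 0.0616, adjusted p = 8.37e-10 by Fisher's exact test). T cell lineage transcription factors had 5 of 40 genes (Klf13, Lef1, Stat5b, Zfp36 and Zfp36l1, odds ratio 5.14, adjusted p = 0.0219 by Fisher's exact test). The list named for the RUNX family and its cofactor had 2 of 7 (Runx1t1 and Runx2, odds ratio 14.3, adjusted p = 0.0472 by Fisher's exact test). Both peaks had scores under the peak list's lower quartile of 9. They lay far from the TSS, that of Runx1t1 at 157.4 kb in a LINE repeat and that of Runx2 at 81.4 kb. CD4 and regulatory T cell genes had 3 of 20 (odds ratio 6.34, adjusted p = 0.0485 by Fisher's exact test), namely Ctla4, Cxcr5 and Il2ra, all of them also in lists above. The neuron list, fixed as a control, passed as well with 4 of 30 genes (Dlg4, Gad2, Nefl and Slc17a6, odds ratio 5.53, interval 1.4 to 16, adjusted p = 0.0318 by Fisher's exact test), the same count as the exhaustion list. The lineage factor, RUNX, CD4 and neuron lists did not pass with territory length in the model, where their odds ratios were 3.62, 9.36, 6.64 and 3.52 in that order. Lineage factor and CD4 genes also did not pass beyond 5 kb (adjusted p = 0.173 and 0.193 by Fisher's exact test). Nor did they with at least the median score (adjusted p = 0.0715 and 0.522 by the exact test). CD4 genes also did not pass with host gene assignment (adjusted p = 0.0539 by the exact test).

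For promoter peaks, 4 lists had a peak more often than other genes, and olfactory receptor genes less often (0 of 1104, a count that allows up to 0.272%, adjusted p = 3.83e-14 by Fisher's exact test). Ribosomal protein genes had a promoter peak in 14 of 83 cases (odds ratio 6.65, interval 3.44 to 12, adjusted p = 2.59e-06 by Fisher's exact test) and spliceosome genes in 9 of 58 (odds ratio 5.98, interval 2.57 to 12.4, adjusted p = 0.000554). Rpl37, Rps13 and Rpl6, which encode proteins of the large and small ribosomal subunits, had peaks of 79, 64 and 52, and Snrpe and Prpf6, parts of the splicing machinery, peaks of 74 and 46. Apoptosis genes had 5 of 31 (Bcl2l1, Bid, Birc3, Cflar and Diablo, odds ratio 6.23, interval 1.86 to 16.5, adjusted p = 0.0163 by Fisher's exact test). Cytokine receptor and JAK-STAT genes had 5 of 38 (Ifnar1, Ifngr1, Stat3, Stat5a and Tyk2, odds ratio 4.90, interval 1.49 to 12.7, adjusted p = 0.0324 by Fisher's exact test). Ifnar1, a chain of the type I interferon receptor, had the highest score among them, 66 (chromosome 16, 91484976 to 91485115). Among peaks with at least the median score, apoptosis genes (2 genes, odds ratio 3.94, adjusted p = 0.492 by Fisher's exact test) and cytokine receptor genes (3 genes, odds ratio 4.91, adjusted p = 0.165) did not pass. Nor did cytokine receptor genes with the smaller background (odds ratio 4.34, adjusted p = 0.0636 by Fisher's exact test).

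Between genes with promoter peaks alone and genes with distal peaks alone, 4 lists differed in a test chosen after seeing the data (Fisher's exact test, adjusted over 18 lists). T cell receptor signalling had 1 gene against 11 (adjusted p = 0.0193), effector genes 1 against 10 (adjusted p = 0.0252), adhesion genes 2 against 11 (adjusted p = 0.0419) and ribosomal protein genes 14 against 1 (adjusted p = 0.0193), all by that exact test. Exhaustion genes, at 0 against 4, did not pass (adjusted p = 0.112), nor did memory genes, at 1 against 6 (adjusted p = 0.114), nor spliceosome genes, at 8 against 1 (adjusted p = 0.112, exact test throughout). Nor did the other lists that passed for promoter peaks, apoptosis at 4 against 1 (adjusted p = 0.618, exact test) and cytokine receptor genes at 5 against 4 (adjusted p = 1).

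With all peaks counted, 10 of the 30 lists were nearest to peaks more often than other genes. These were the effector (11 of 31, adjusted p = 4.56e-06), adhesion (13 of 42, adjusted p = 3.87e-06), T cell receptor (12 of 41, adjusted p = 1.1e-05), memory (7 of 32, adjusted p = 0.00534), cytokine receptor (9 of 38, adjusted p = 0.000933), lineage factor (8 of 40, adjusted p = 0.00525), RUNX (3 of 7, adjusted p = 0.0138), apoptosis (6 of 31, adjusted p = 0.0163), ribosomal protein (15 of 83, adjusted p = 0.000286) and spliceosome lists (10 of 58, adjusted p = 0.00525), by Fisher's exact test. Exhaustion genes did not pass with all peaks (4 of 30, odds ratio 2.62, adjusted p = 0.166 by the exact test). Within 50 kb of a TSS they had 2 genes (odds ratio 1.37, adjusted p = 0.762 by the exact test). Olfactory receptor genes (2 of 1104, odds ratio 0.0291, adjusted p = 9.64e-24) and keratin genes (0 of 109, a count that allows up to 2.75%, adjusted p = 0.0138) had peaks less often by the same exact test. Limited to peaks within 10 kb of a TSS, the T cell receptor (odds ratio 3.45 instead of 7.08, adjusted p = 0.0687 by Fisher's exact test), effector (3.68 instead of 9.41, 0.0844), memory (3.55 instead of 4.77, 0.0858), RUNX (4.13 instead of 12.8, 0.485) and keratin lists (0 in both, 0.0693) did not pass. With at least the median score, the memory (odds ratio 3.42, adjusted p = 0.184 by the exact test), RUNX (5.49, 0.405), apoptosis (2.27 instead of 4.09, 0.435) and keratin lists (0, 0.201) did not pass, and the RUNX list also failed within 50 kb (3.19, 0.532) and outside repeats (7.58, 0.103).

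The other lists did not pass for any class of peaks as reported. Under alternatives, NF-kB pathway genes passed for all peaks within 10 kb of a TSS (odds ratio 4.97, adjusted p = 0.0485 by Fisher's exact test), and oxidative phosphorylation genes for promoter peaks with at least the median score (6 of 86, odds ratio 4.32, adjusted p = 0.0281). With all peaks, 4 of 24 NF-kB pathway genes had one (Birc3, Map3k14, Relb and Traf1, adjusted p = 0.0961 by Fisher's exact test), 3 of 26 AP-1, BATF and IRF genes (Irf1, Junb and Maf), 2 of 26 ETS family genes (Elk4 and Fli1), 3 of 50 cell cycle genes (Mcm3, Mcm4 and Tk1) and 1 of 44 interferon-stimulated genes (Psmb9). Promoter peaks were at 7 of 86 oxidative phosphorylation genes (adjusted p = 0.0757 by Fisher's exact test), 3 of 48 proteasome genes, 2 of 78 mitochondrial ribosomal protein genes and 1 of 59 translation factor genes. For cells that a spleen preparation could add, distal peaks were near 0 of 26 B cell genes, 0 of 27 erythroid and megakaryocytic genes and 0 of 20 endothelial genes. These counts allow up to 11.5%, 11.1% and 15.0%, against 2.72% of all background genes, so they do not speak against such cells. Distal peaks were near 2 of 34 myeloid genes (Itgax and Tyrobp) and 1 of 17 NK cell genes (Tyrobp). Of the lists of such cells, that of CD4 and regulatory T cells did pass, as given above (3 of 20). Of the hepatocyte genes, a control list, 1 of 25 had a distal peak (Apoa1).

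Of 24 genes fixed in advance as points of interest, 8 were nearest to a peak. These were Cd28, Fli1, Gzmb, Havcr2, Ifng, Prdm1, Runx3 and Tox. Runx3, a RUNX factor of CD8 T cells, was the only one with a promoter peak, at -215 bp with a score of 19 (chromosome 4, 135120390 to 135120470). Fli1 itself had 2 peaks in intron 1 of 8, 2.1 and 41.8 kb from its TSS, with scores of 5 and 7 (chromosome 9, 32539349 to 32539399 and 32499608 to 32499693). The 16 without a peak were the transcription factor genes Ets1, Runx1, Tcf7, Id3, Tbx21, Eomes, Batf and Nr4a1, the receptor genes Cxcr3, Cx3cr1, Pdcd1, Il7r, Cd3e, Cd8a and Klrg1, and Bcl2. A list of called peaks does not show that Fli1 is absent from those genes, since weaker signal stays under the caller's threshold.

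Several genes were nearest to clusters of peaks. Of 1304 genes nearest to a peak, 13 were nearest to 3 or more. Pisd-ps3 had 18, on an unplaced contig and mostly in satellite repeats, and Mir101c had 7, in satellite repeats of chromosome 9. Rplp1, which encodes a ribosomal stalk protein, had 5, all between 206.4 and 244.4 kb from its TSS. Rgs3, a regulator of G protein signalling, had 4 intron peaks, and Ski, a repressor of TGF-beta signalling, had 3 in intron 1 of 6 with scores of 53, 93 and 41. The Ski peak of 93 lay in an LTR repeat. Gm29679, Mob3a, Hivep2, Gm12596 and Arhgap25 had 3 each. For Gm29679, all 3 peaks lay in introns of another transcript, 56.2 to 66.1 kb from the named TSS.

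Chromosome X carried few peaks, 9 of 1447 (0.622%, interval 0.328 to 1.18). Of its 905 coding genes, 7 were nearest to a peak (0.773%, interval 0.375 to 1.59), against 1163 of 20044 on the autosomes (5.80%, interval 5.49 to 6.13). The odds ratio was 0.127 (interval 0.0506 to 0.263, p = 5.87e-15 by Fisher's exact test, two-sided, chosen after seeing the counts). Promoters of Bcap31, an endoplasmic reticulum protein, and Rlim, a ubiquitin ligase, held the highest scores on X, 76 and 59. No peak lay nearest to any of the 78 coding genes on chromosome Y.

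**Figure D4:**
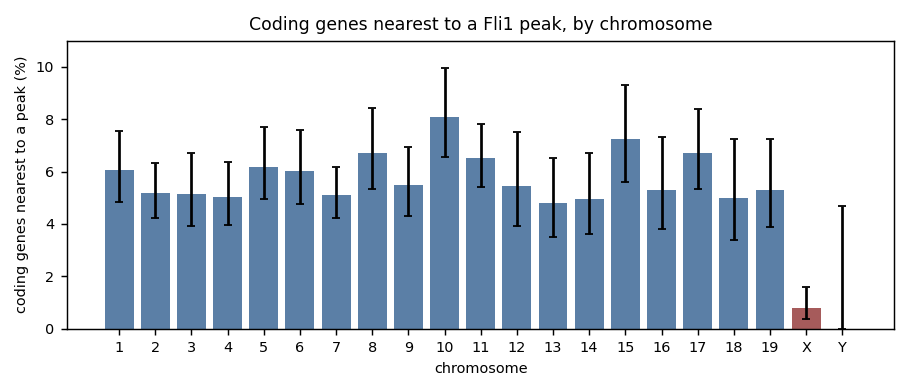
Share of coding genes nearest to at least 1 Fli1 peak (percent) on each chromosome, with Wilson 95% intervals; autosomes are blue and the sex chromosomes red. Chromosome X stands at 0.773%, against 5.80% over the autosomes.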

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

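All tests in this part were chosen after the results were seen. On unplaced sequence there were 19 peaks with a median score of 52, against 16 for peaks that were neither there nor in satellites. Satellite repeats held 26 peaks with a median score of 43, and satellite or unplaced peaks were 3 of the 10 strongest and 9 of the 50 strongest. The antigen receptor loci with 10 kb either side, whose gene segments are not among the coding genes, had 9 peaks, 6 of them inside the bounds of the segments and 3 in the flanks. In the gene comparisons, 6 of the 9 counted under a neighbouring coding gene, such as Dad1, and 3 were not counted. Of the 9, 3 were at the T cell receptor alpha and delta locus, including one with a score of 15 in the flank, 3132 bp from the constant gene Trac (chromosome 14, 54227330 to 54227733). Another 2 were at the beta locus, including one with a score of 17 (chromosome 6, 41554436 to 41555030), and 1 was at the gamma locus. The immunoglobulin heavy chain locus held 3, the strongest with a score of 60 at 895 bp from Ighj4 (chromosome 12, 113427382 to 113427619), and the light chain loci 0.

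The effector, exhaustion, memory, T cell receptor and adhesion lists were pooled after each had passed for distal peaks. Together they had distal peaks near 40 of 169 genes (odds ratio 11.8, interval 8 to 17.2). With territory length in the model the odds ratio was 10.7 (interval 7.37 to 15.5), so territory length as measured here does not account for it. That measure is a single log term from gene spans without strand, while peaks were assigned by the nearest TSS. A part played by territory that this measure misses stays open. Repeats near these genes do not account for the high odds ratio of the lists, which was 14.4 (interval 9.60 to 21.0) outside repeats. Cutting at open chromatin whatever the antibody may give the same lists and stays open, because 0 IgG peak lists or accessibility maps of these cells were used here. Binding of Fli1 near T cell genes remains a hypothesis, which the labelled groups could test with values per library.

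The low share of peaks on chromosome X does not come from receptor families and predicted genes, since without them the odds ratio was 0.132 (interval 0.0527 to 0.274). A single copy of X could lower the signal, if the mice were male, but their sex is not given in the sources used here. Were the score proportional to signal, X peaks scoring at least 16 should be as frequent per gene as autosomal peaks scoring at least 32, and their ratio was 0.386 (interval 0.124 to 0.911). With scores of 9 and 18 the ratio was 0.273 (interval 0.118 to 0.542), and with 29 and 58 it was 0.471 (interval 0.0562 to 1.75), on 2 X peaks. As the last interval includes 1 and the score's scale is unknown, copy number stays open, and no biological explanation was tested.

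Promoter shares differed over the 6 lists of constitutive genes (permutation p = 0.00278), so these promoters did not all hold peaks alike. The 6 lists include the ribosomal protein and spliceosome lists, which had already passed. The test therefore cannot exclude reads collected at constitutive promoters as a source of these calls. These 2 lists, picked because they had passed, had 23 of 141 genes with a promoter peak against 13 of 271 in the other 4 (odds ratio 3.85, interval 1.80 to 8.59). Against oxidative phosphorylation genes alone (7 of 86) the odds ratio was 2.19 (interval 0.859 to 6.35) and against proteasome genes alone (3 of 48) 2.91 (interval 0.818 to 15.9), so a difference from those groups was not shown, and oxidative phosphorylation genes themselves passed among peaks with at least the median score (odds ratio 4.32). Weak peaks do not carry the pattern, since among peaks with at least the median score the odds ratio of the 2 lists against all other genes was 10.5 (interval 6.20 to 17.0), against 6.47 with all promoter peaks. Transcription was not measured here, so high transcription stays open as a source of reads, and no biological explanation was tested.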

How the results depend on the processing

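The T cell receptor, effector and adhesion lists passed for distal peaks under all 5 alternatives run for those peaks, and the ribosomal protein and spliceosome lists passed for promoter peaks under all 4 run for those. The territory model, repeat filter and host gene assignment for distal peaks, host gene assignment for all peaks and the smaller background for promoter peaks were chosen after seeing the data. Lists with more distal peaks fell from 9 to 4 with at least the median score, and to 4 with the territory model, in both cases from among the 9. The median score limit leaves 268 genes with a distal peak instead of 572. With peaks beyond 5 kb 6 lists passed, and outside repeats and with host gene assignment 7 each. Lists with fewer peaks fell from 2 to 1 for all peaks within 10 kb, with at least the median score, and with the smaller background, and from 1 to 0 for promoter peaks with the smaller background, which leaves out the olfactory receptors. The promoter share of 43.7% became 49.3% with at least the median score and 46.7% by distance within 1 kb, and the share within 1 kb of 46.9% became 52.7% with at least the median score; the cause was not tested. Odds ratios that changed side were those of exhaustion genes within 10 kb (0.853), of effector and memory genes at promoters with the smaller background (0.95 and 0.919), and of the RUNX list for distal peaks with at least the median score (0, with 0 genes), where few genes had a peak. Of the remaining list values, 140 kept their direction and side of the threshold and 30 no longer passed. The NF-kB list, for all peaks within 10 kb, and the oxidative phosphorylation list, for promoter peaks with at least the median score, passed only there.

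The RUNX list passed for distal peaks only as reported and with peaks beyond 5 kb. By Fisher's exact test, the neuron list passed beyond 5 kb (odds ratio 6.88, adjusted p = 0.0202) and with host gene assignment (odds ratio 5.31, adjusted p = 0.0364). Host gene assignment used the deposited annotation, which placed both Gad2 peaks between genes, so neither was reassigned. The wider one, of 1494 bp, lay over another coding gene, Myo3a. The neuron list did not pass with at least the median score (2 genes, odds ratio 5.57, adjusted p = 0.232 by Fisher's exact test). Nor did it pass outside repeats (3 genes, odds ratio 5.10, adjusted p = 0.0864 by Fisher's exact test) or with the territory model (4 genes, odds ratio 3.52). As reported, its odds ratio was 5.53. No paired analysis was possible because the results come from 1 pooled list with no values per library, and leaving out each replicate was not run for that reason. All planned motif alternatives were not run, as no genome was used here. Unknown depth limits every statement about a gene without a peak.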

Other observations

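All tests in this part were chosen after seeing the data. Among 274 families of coding genes that share the start of their symbol, 2 more stood out for promoter peaks beside the receptor and predicted gene families, which had fewer. Symbols starting with Rps had promoter peaks in 8 of 44 cases (odds ratio 7.22, interval 2.89 to 15.9, adjusted p = 0.00304 by Fisher's exact test). All 8 were among the 31 that are in the ribosomal protein list, and the other 13, mostly ribosomal S6 kinase genes, had 0. Symbols starting with Mcm had 4 of 10 (odds ratio 21.6, interval 4.46 to 91.2, adjusted p = 0.00815 by the same exact test), namely Mcm3 and Mcm4, subunits of the replicative helicase, Mcm10, a replication factor, and Mcm3ap, which acts in mRNA export. With all peaks, symbols starting with Sp had 5 of 12 (odds ratio 12.2, interval 3.04 to 44.6, adjusted p = 0.0206 by the exact test), namely the zinc finger factors Sp1, Sp2, Sp3 and Sp6 and the nuclear body protein Sp100. For distal peaks, Pik genes (4 of 16, adjusted p = 0.104) and Arhgap genes (5 of 34, adjusted p = 0.144) did not pass the exact test.

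Of all peaks, 188 (13%, interval 11.4 to 14.8) were annotated to a repeat. Endogenous retroviral LTR elements held 80, of which 32 were of the ORR1 type with a median score of 17.5, and LINE elements held 51 with a median score of 9. The widest peak spanned 4549 bp (chromosome 1, 24611581 to 24616129, score 98) over the pseudogenes Gm10222 and Gm10925, the latter with the mitochondrial gene name mt-Atp6 among its synonyms.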
